A study of Homo sapiens with 17 samples.

How the data were processed

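Total RNA from 17 samples of MCF-7 cells, grown in DMEM with fetal calf serum, was turned into biotin-labelled cRNA and measured on Affymetrix HG-U133 Plus 2.0 arrays, per the labels' protocols. The authors deposited a table of signal values on a linear intensity scale for 54675 probe sets and 17 arrays. These intensities were made with MAS5, per the submitters' processing notes, with no version given. MAS5 summarises each probe set from perfect-match and mismatch probes, so values near its floor vary much from array to array. The mean after leaving out 2% of the values at each end was 150.02 on every array, so the deposited intensities were already scaled to a common mean, and rescaling moved nothing. No read counts lie behind such values, and the number of arrays limits the precision.

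The samples were assigned to 10 groups by their titles. Untreated cells and Argyrin A at 24 h had 3 arrays each, Argyrin A at 12 h, siRNA at 12 h and siRNA at 24 h had 2 each, and Argyrin A at 14 h and 48 h and bortezomib at 14 h, 24 h and 48 h had 1 each. The titles of 10 arrays carried the number 1 or 2 and those of 7 arrays carried none, and each of these series held untreated cells and Argyrin A at 24 h. For the 3 Argyrin A arrays without a number, a separate treatment label gave the trade name of bortezomib, while the title, the description and the source named Argyrin A, and the title was followed. The labels gave no dose, siRNA target, mock transfection, vehicle control or time for untreated cells, so treatment and culture time are not separated. Nothing in the labels said that arrays of 1 group came from separate cultures. The p-values thus measure only the spread between these arrays, which may be technical.

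Probe sets were named from the platform annotation, in which 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Of the first, 41043 matched a RefSeq gene table of GRCh38.p14 by Entrez identifier, which changed 0 symbols. That table served for names only. Genes measured only by probe sets with several symbols are not named, among them HSPA1A, PSMA6, PSMC5 and UBC. Probe sets of XIST were left out. Each of 19774 genes was represented by its own probe set with the highest mean over the 17 arrays, and other probe sets of a named gene are mentioned where they moved the opposite way. A gene was tested where that mean was at least 20% of the common trimmed mean (a signal of 30.0), which left 12558 genes.

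Signals were analysed as log2(signal + 15.0), an offset of 10% of the common trimmed mean. A fold change is on that scale, so that the size of a dim gene's change depends on the offset. The linear model of limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to all 17 arrays with a mean for each of the 10 groups and a term for the series (titles with or without a number), so that the groups shared 1 estimate of the spread, with 6 residual and 3.82 prior degrees of freedom. The bortezomib arrays all belonged to the unnumbered series, and the model set them against untreated cells after estimating the series difference from the groups present in both. Where a group had 1 array, that array was assumed to vary like the replicated groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Tests were two-sided. Tables were read with the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

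The 10 comparisons, the rule for named genes, 28 gene lists and the alternatives were written down before the data were examined, except where an alternative is said to have been added. The lists covered 20S, 19S and immunoproteasome subunits, ubiquitin and autophagy adaptors, heat shock, endoplasmic reticulum (ER) stress, ATF4, NRF2, metallothionein, p53, S phase, mitosis, G1, estrogen receptor, apoptosis, NF-kappaB, interferon, cholesterol, hypoxia, immediate early, histone, cytosolic ribosomal, ribosome biogenesis and oxidative phosphorylation genes, and markers of luminal, basal, fibroblast and leukocyte cells. Some genes stood on several lists. A list with at least 4 tested members was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists tested in a comparison, and again with the correlation estimated from the data. The median in the text is the median log2 difference over a list's tested members. The count of members called was also made with p adjusted over the list alone. Of the 90 list calls over the 10 comparisons, 1 held with an estimated correlation.

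The text names, for each comparison, up to 10 of the largest rises and of the largest falls among called genes whose every treated array lay on 1 side of every control array of the same series. It also names up to 4 of the called members with the largest change on each list described, and CDKN1B, CDKN1A, SKP2, CKS1B, PSMB5, PSMB6, PSMB7, PSMA7, HMOX1, DDIT3, CCNB1, CCNE2 and TFF1 throughout. Where fewer than 5 genes passed in a direction, the 5 with the largest moderated statistic are given as values only. Genes named for another reason are said to have been chosen after their values were seen.

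The model was tested on simulated data in which 100 genes per size were changed. At a log2 change of 2 it called 80% of changed genes for Argyrin A at 12 h, 96% for Argyrin A at 24 h, 83% for siRNA at 12 h, 82% for siRNA at 24 h and 85% for bortezomib. At a log2 change of 1 it called 13%, 34%, 12%, 9% and 13% of them in the same order. For siRNA against Argyrin A the shares were 97% and 56%.

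The alternatives were offsets of 2.5% and 20% of the trimmed mean, quantile normalization, the values without rescaling, no filter and a filter at 50%, the mean of a gene's probe sets or the probe set with the highest median, no series term, the title number as a block, only the groups compared, only the 10 numbered arrays, the 3 time points of a compound as replicates, eBayes with trend and robust settings, and each array left out in turn. The numbers 1 and 2 in the titles were taken to pair the arrays, since the deviations from the group means of arrays of the same number correlated at 0.104 or more in each of 10 pairs of groups (highest 0.540, median 0.297). This pairing comes from the data, as the labels do not say what the number marks. The fit with the number as a block is given beside a result where it changed the call. List tests without bortezomib at 14 h were added after the data had been seen. RNA quality was read from the ratio of the 3 prime to the 5 prime control probe sets of ACTB and GAPDH. Correlations of fold changes between comparisons that share untreated arrays were set beside the mean of 100 simulations with unchanged groups.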

Results

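By their labels, the samples were MCF-7 cells, an established line of estrogen receptor-positive luminal breast adenocarcinoma. They were left untreated, exposed to bortezomib, a boronic acid dipeptide that inhibits the proteasome, exposed to Argyrin A, a cyclic peptide of myxobacteria that also inhibits the proteasome, or given small interfering RNA (siRNA) against proteasome subunits. The comparisons ask which transcripts each treatment moved and how far the response to Argyrin A resembled those to bortezomib and to siRNA. Transcripts of 12558 genes were tested on 17 arrays, and values after ± are standard errors (SE) for log2 differences and standard deviations (SD) for signals. Median signals lay between 25.1 and 36.7 on every array. The 10 numbered arrays had ACTB 3 prime to 5 prime ratios of 1.19 to 2.17, where higher ratios mark RNA broken from its 5 prime end. In the unnumbered series the ratio was 5.34 in untreated cells, 3.83, 1.95 and 3.24 after Argyrin A for 14 h, 24 h and 48 h, and 1.71, 14.7 and 6.96 after bortezomib for 14 h, 24 h and 48 h. The GAPDH ratio was 3.36 in the bortezomib 24 h array and between 0.931 and 2.25 in all others.

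The array labelled bortezomib 14 h stood apart from the rest. Its correlation with the untreated array of its own series was 0.739 across genes, against 0.876 and 0.857 for bortezomib at 24 h and 48 h and 0.969 to 0.974 for the 3 Argyrin A arrays of that series. On it, 43 genes were bright that were dim on every other array and 15 genes were dim that were bright on every other array, and no other array had such genes. Among them, chosen after their values were seen, LDHB had a signal of 8983 there against at most 87.8 elsewhere and CDKN2A one of 1516 against at most 99, while KRT19, a keratin of luminal cells, had 46.3 there against at least 6358 elsewhere. For this reason the counts of genes past the threshold and of list members are also given without that array, an alternative added after the data had been seen.

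**Figure D1:**
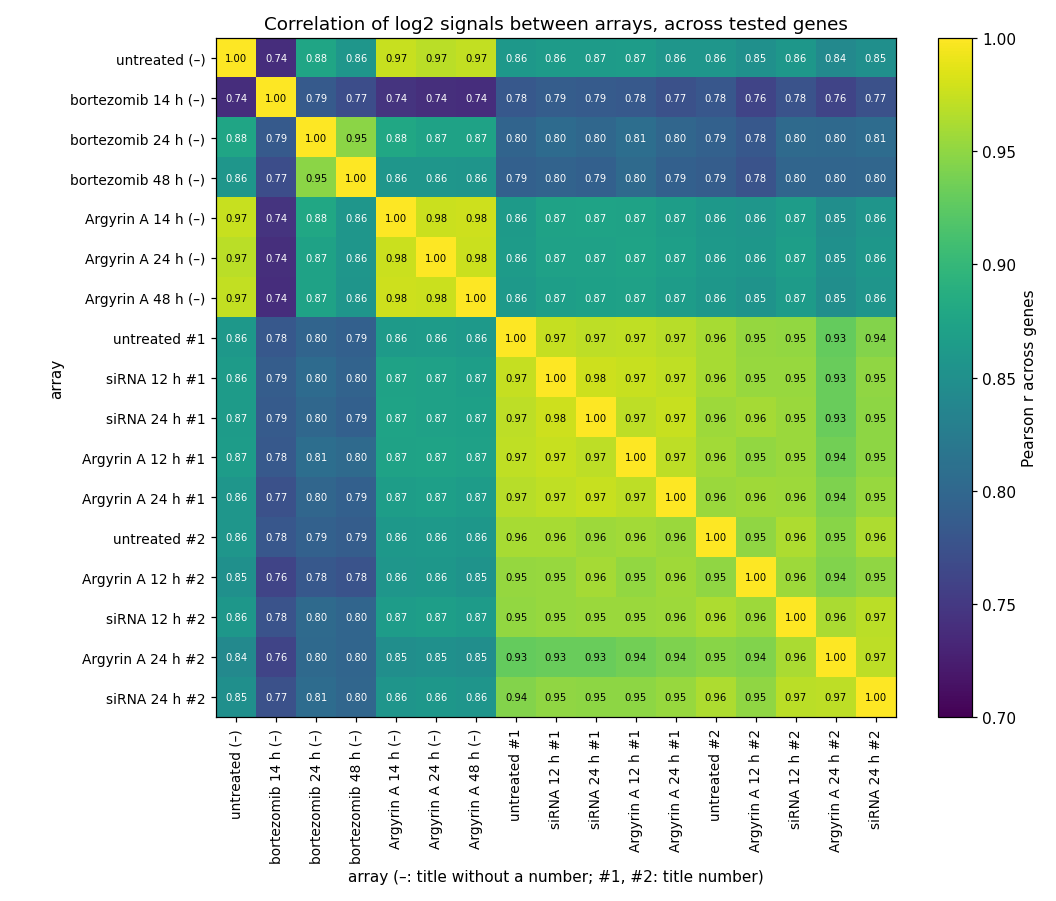
Pearson correlation of log2 signals across the tested genes for each pair of the 17 arrays, ordered by series and coloured by r. The bortezomib 14 h array is darker against all others, with r of 0.739 to its own untreated array. The 3 Argyrin A arrays of that series have 0.969 to 0.974 to that array.

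Bortezomib was set against untreated cells as the mean of 14 h, 24 h and 48 h, with 1 array per time. Of 18 heat shock genes 13 rose (list test adjusted p = 7.86e-10, or 0.0524 with an estimated correlation), led by HSPA6, an inducible member of the HSP70 family, whose signal was 11768 ± 4667 (SD, n = 3 times) after bortezomib against 12.9 ± 11.4 (SD, n = 3) in untreated cells. Its log2 difference was 9.88 ± 1.31 in the fit and 9.2, 9.67 and 8.45 on the 3 arrays against the untreated array of the series. Untreated signals of 5.20, 7.40 and 26.0 lay around the offset of 15.0, on which that size depends (11.19 and 8.98 with offsets of 2.5% and 20% of the common trimmed mean). The cochaperone DNAJB1 rose from 1242 ± 537 to 11382 ± 2328, by 2.76 ± 0.31 on the log2 scale. ESR1, which encodes the estrogen receptor, fell from 1585 ± 280 to 114 ± 98.0, a log2 difference of -3.84 ± 0.31, and remained lower without the 14 h array at -3.19 ± 0.33. At 24 h and 48 h, RRM2, a subunit of ribonucleotide reductase, had signals of 60.2 and 59.6 against 2804 in the untreated array of the series. At 14 h the RRM2 signal was 4683.

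In limma's test 2829 of 12558 genes passed, 1059 higher and 1770 lower, of which 759 and 1405 changed by at least 2-fold. Without the 14 h array 2445 passed, 898 higher and 1547 lower, and 1865 of them had been called with it in the same direction. The count rested on the single untreated array of the unnumbered series, since 540 genes passed when it was left out, and it was 675 in a fit to these 6 arrays alone. A direct test of 14 h against the mean of 24 h and 48 h called 3497 genes. That of 48 h against 24 h called 0 in limma's test, with 1283 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0624.

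The largest rises were those of HSPA6 (adjusted p = 0.00103), the chemokine CCL26 (log2 4.85 ± 0.37), the autophagy gene GABARAPL1 (4.57 ± 0.35), the stress transcription factor ATF3 (4.31 ± 0.95). After them came the small heat shock protein CRYAB (4.20 ± 0.55), NDRG1 (4.02 ± 1.07), the MAP kinase phosphatase DUSP1 (3.96 ± 0.33), INHBA, a subunit of activin (3.92 ± 0.42), RGS2 (3.84 ± 0.43) and ZFAND2A, an arsenite-inducible proteasome-associated zinc finger protein (3.81 ± 0.47). The other probe set of DUSP1 moved the opposite way. The largest falls were those of AGR3 (-6.97 ± 0.42), the matrix protein MGP (-5.66 ± 0.79), SOX3 (-5.28 ± 0.72), CLIC3 (-5.25 ± 0.25, adjusted p = 1.86e-05), AMIGO2 (-5.14 ± 0.52), HMCN1 (-5.11 ± 0.33), RAMP3 (-5.10 ± 0.53), IGFBP5 (-5.05 ± 0.39), CCN5 (-5.02 ± 1.29) and GATA3-AS1 (-5.00 ± 0.38). All 20 kept their direction and their call without the 14 h array. AGR3, HMCN1, RAMP3 and, named below, LINC00052 were dim on all numbered arrays, so their falls rest on the unnumbered series.

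Adjusted over the list alone 15 of 18 heat shock genes rose, and the list had a median log2 difference of 1.88. Besides HSPA6, CRYAB and DNAJB1 they included HSPB8 (2.77 ± 0.26), whose signals were 204, 2605 and 1999 at 14 h, 24 h and 48 h, all above the untreated array of the series. Its log2 difference was -0.58 without the series term. Leaving out the 14 h array gave the list a median of 1.35, with adjusted p = 3.13e-10 and adjusted p = 0.0457 with an estimated correlation. Of 17 ubiquitin and autophagy adaptor genes 9 rose (11 adjusted over the list alone). The median was 0.78 over the whole list, with adjusted p = 3.97e-06, or 0.0524 with an estimated correlation. GABARAPL1, ZFAND2A, UCHL1 (2.45 ± 0.54) and MAP1LC3B (2.09 ± 0.31) led them, and UCHL1 lost its call without the 14 h array, at 1.21, while the list's median was then 1.31. Of 20 immediate early genes 7 rose (7 adjusted over the list alone), among them ATF3, DUSP1, MAFF (3.80 ± 0.30) and FOSL1 (2.70 ± 0.37). The median was 0.66 over the whole list, with adjusted p = 0.00665, or 0.0793 with an estimated correlation.

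Genes of the proteasome itself moved less. None of the 18 genes of the 19S regulatory particle and none of the 13 of the 20S core passed in limma's test, with medians of 0.47 and 0.18. The list test gave adjusted p = 0.0171 for 19S (adjusted p = 0.535 with an estimated correlation) and adjusted p = 0.179 for 20S. Without the 14 h array 5 genes of the 19S particle rose (10 adjusted over the list alone), with a median of 0.80 and adjusted p = 5.62e-05, or 0.293 with an estimated correlation. In that fit 1 gene of the 20S core rose, with a median of 0.49 and adjusted p = 0.00116, or 0.480 with an estimated correlation. The 5 were PSMD12 (1.36 ± 0.32), PSMC4 (1.20 ± 0.31), PSMC6 (1.20 ± 0.25), PSMD14 (1.01 ± 0.30) and SEM1 (0.90 ± 0.23), and the 1 was PSMB7 (1.13 ± 0.28). PSMD12 had signals of 3415 at 14 h, 9666 at 24 h and 11872 at 48 h, against 3415 in the untreated array of the series. The 3 measured genes of the immunoproteasome and its activator, too few for a list test, all fell: PSMB9 by -1.92 ± 0.38, PSME1 by -1.62 ± 0.28 (-1.07 ± 0.31 without the 14 h array) and PSMB10 by -1.62 ± 0.26.

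Of 25 ATF4 targets, genes of amino acid supply and stress, 7 rose (8 adjusted over the list alone). The median was 1.41 over the whole list, with adjusted p = 2.20e-05, or 0.535 with an estimated correlation. SLC7A11, the cystine transporter, stood at 3.71 ± 0.97 and CTH at 3.68 ± 0.89, while PSAT1, at 3.06 ± 0.75, lost its call without the 14 h array, at 0.99, and stood at -0.72 without the series term. Of 19 NRF2 targets 6 rose and 2 fell (7 and 2 adjusted over the list alone). The median was 0.43 over the whole list, with adjusted p = 0.0166, or 0.633 with an estimated correlation. They included HMOX1, heme oxygenase (3.57 ± 1.10, adjusted p = 0.0436), TXNRD1 (2.26 ± 0.60) and ABCC3 (-2.67 ± 0.59, or 0.12 from the probe set with the highest median). The list's median was 1.38 without the 14 h array, with 8 higher and 1 lower. Of 20 ER chaperone and unfolded protein response genes ERN1 rose (1.75 ± 0.46) and XBP1 fell (-1.49 ± 0.27, with its other probe set moving the opposite way). The median was 0.77 over the whole list, with adjusted p = 0.0316, or 0.633 with an estimated correlation. Of 21 hypoxia targets 4 rose, NDRG1, ADM (3.43 ± 0.75), KDM3A (1.98 ± 0.53) and P4HA2 (1.94 ± 0.45). The median was 0.89 over the whole list, with adjusted p = 0.00281, or 0.535 with an estimated correlation.

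Of 28 mitosis genes 20 fell (25 adjusted over the list alone). The median was -2.05 over the whole list, with adjusted p = 2.76e-10, or 0.467 with an estimated correlation. The list median was 0.11 at 14 h, -2.53 at 24 h and -2.91 at 48 h, and without the 14 h array 25 fell, with a median of -2.83. CDK1, the mitotic kinase, had signals of 1984, 112 and 17.7 at 14 h, 24 h and 48 h against 1750 in the untreated array of the series (-3.05 ± 0.37). DLGAP5 (-3.44 ± 0.54), CDC20 (-3.04 ± 0.43) and TOP2A (-3.01 ± 0.40) fell with it. Of 27 S phase genes 14 fell (19 adjusted over the list alone). The median was -1.07 over the whole list, with adjusted p = 2.38e-07, or 0.467 with an estimated correlation. They included RRM2 (-3.54 ± 0.29), TK1 (-2.88 ± 0.24), UHRF1 (-2.58 ± 0.57) and GINS2 (-2.45 ± 0.39). The S phase medians were 0.94, -2.03 and -2.23 at the 3 times, and without the 14 h array 25 fell, with a median of -2.19. That fit put CDK1 at -4.70 ± 0.40, RRM2 at -5.53 ± 0.32, UHRF1 at -4.64 ± 0.62 and GINS2 at -3.69 ± 0.43. Between the array at 14 h and the mean of the later ones, 26 of 27 S phase genes and 24 of 28 mitosis genes were higher at 14 h in limma's test. The 24 h array was also the one with the ACTB ratio of 14.7.

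Of 11 histone genes 10 fell (11 adjusted over the list alone). The median was -1.74 over the whole list, with adjusted p = 2.38e-07, or 0.0793 with an estimated correlation. In front stood H2AC6 (-3.10 ± 0.49), H2AJ (-3.03 ± 0.32), H2BC21 (-2.99 ± 0.36) and H2BC5 (-2.66 ± 0.40), the last 2 at -1.82 ± 0.39 and -1.75 ± 0.43 without the 14 h array. Of 24 estrogen receptor targets 17 fell (17 adjusted over the list alone). The median was -1.70 over the whole list, with adjusted p = 2.12e-09, or 0.0524 with an estimated correlation. Besides ESR1 they included MYB (-3.01 ± 0.46), TFF3 (-2.95 ± 0.69) and CXCL12 (-2.88 ± 0.52). Without the 14 h array 14 of them fell, with a median of -1.40. TFF1, which estrogen induces, fell by 0.86 ± 0.23 with the 14 h array, where its signal was 736, and stood at 0.73 without it (adjusted p = 0.0687), with signals of 19076 at 24 h and 21518 at 48 h against 11969 in the untreated array of the series. Of 16 luminal markers 13 fell (14 adjusted over the list alone). The median was -1.80 over the whole list, with adjusted p = 4.18e-10, or 0.0524 with an estimated correlation. At 24 h and 48 h alone 7 fell and the median was -0.54. MUC1 (-3.91 ± 0.44) and SPDEF (-3.14 ± 0.29, 2 of its 4 other probe sets moving the opposite way) were among them, and KRT19 went from -3.18 ± 0.25 to -0.88 ± 0.27 without the 14 h array.

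Of 8 metallothioneins 6 fell, among them MT1H (-2.66 ± 0.57), MT2A (-2.49 ± 0.47), MT1X (-2.37 ± 0.53) and MT1F (-1.75 ± 0.44). The median was -1.71 over the whole list, with adjusted p = 0.00281, or 0.467 with an estimated correlation. Of 23 interferon response genes 7 fell, among them OAS1 (-3.25 ± 0.83), OAS3 (-2.91 ± 0.91), RIGI (-2.49 ± 0.74) and IFI35 (-1.94 ± 0.35). The median was -1.27 over the whole list, with adjusted p = 0.0316, or 0.633 with an estimated correlation. That call ended without the 14 h array, at adjusted p = 0.119, as did that of RIGI (-1.59, adjusted p = 0.194). Of 22 oxidative phosphorylation genes ATP5MC1 (-1.88 ± 0.40) and NDUFV1 (-1.32 ± 0.23) fell. The median was -0.33 over the whole list, with adjusted p = 0.04, or 0.535 with an estimated correlation. Of 18 ribosome biogenesis genes RRP12 (1.71 ± 0.33), DDX21 (1.23 ± 0.25) and NOP58 (0.83 ± 0.22) rose. The median was 0.33 over the whole list, with adjusted p = 0.0171, or 0.467 with an estimated correlation, and adjusted p = 0.124 without the 14 h array, where NOP58 lost its call (0.63, adjusted p = 0.0926). None of 23 cytosolic ribosomal protein genes passed in limma's test, while the list lay higher, with a median of 0.43 and adjusted p = 0.00184, or 0.633 with an estimated correlation.

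Without the 14 h array 13 heat shock, 11 adaptor, 7 immediate early, 6 ATF4, 5 hypoxia and 2 ribosome biogenesis genes rose. In the same fit 9 histone, 6 metallothionein, 4 interferon and 2 oxidative phosphorylation genes fell, and 1 interferon gene rose.

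The other 9 lists did not pass as lists. Of 24 regulators of G1, 2 rose and 8 fell (2 and 10 adjusted over the list alone), with a median of -0.64 and adjusted p = 0.0676 (0.0374 without the 14 h array, or 0.177 with an estimated correlation). CCND1, the cyclin of G1, fell (-2.79 ± 0.38), CCNE2 fell (-1.81 ± 0.40), RBL1 fell (-1.79 ± 0.27) and MYC rose (1.94 ± 0.25). CCNE2 stood at 1.05, -2.32 and -2.71 at 14 h, 24 h and 48 h against the untreated array of the series. Without the 14 h array CCNE2 stood at -3.0 ± 0.43 (adjusted p = 0.00177) and RBL1 at -2.91 ± 0.29. Of 22 p53 targets 3 rose and 3 fell, among them GADD45A (3.72 ± 0.61), GDF15 (3.33 ± 0.64), TNFRSF10B (1.79 ± 0.44) and DDB2 (-2.50 ± 0.43), with a median of -0.16, which was 0.41 without the 14 h array, a mean of 0.15 and adjusted p = 0.983. Of 22 apoptosis regulators TNFRSF10B, TNFRSF10A (1.24 ± 0.28, or 2.51 ± 0.30 without the 14 h array) and MCL1 (0.80 ± 0.24) rose, with a median of 0.09 and adjusted p = 0.357. Of 14 NF-kappaB targets IL6 rose (3.27 ± 0.53) and NFKBIA (-2.51 ± 0.36) and NFKB1 (-0.91 ± 0.23) fell, with a median of -0.20, a mean of 0.04 and adjusted p = 0.855. Of 17 cholesterol synthesis genes 3 rose and 2 fell, among them LSS (-1.90 ± 0.29), SC5D (1.24 ± 0.24), DHCR7 (-1.08 ± 0.31, or -0.47 without the 14 h array, no longer called) and STARD4 (1.01 ± 0.24, or -0.36 without the series term), with a median of -0.04, a mean of 0.01 and adjusted p = 0.594. Markers of other cells gave adjusted p = 0.583 for 4 basal genes, with ITGB4 lower (-3.40 ± 0.37), adjusted p = 0.175 for 4 leukocyte genes, with LCP1 lower (-1.11 ± 0.28), and adjusted p = 0.720 for 8 fibroblast genes. Among the last, FN1 was lower (-1.17 ± 0.29, or 1.92 without the series term) and VIM, vimentin, higher (2.42 ± 0.55), with a VIM signal of 9313 at 14 h against 12.1 and 8.30 at the later times and -0.43 for VIM without the 14 h array.

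CDKN1B encodes p27, an inhibitor of cyclin-dependent kinases that the proteasome degrades, and its transcript stood at -0.66 ± 0.28 after bortezomib (adjusted p = 0.120, or 0.0329 with the title number as a block) and at -0.14 ± 0.31 without the 14 h array. CKS1B, a cofactor in the tagging of p27, fell (-0.84 ± 0.23, adjusted p = 0.0292), with 0.44, -1.51 and -1.57 at 14 h, 24 h and 48 h against the untreated array of the series and -1.50 ± 0.25 without the 14 h array (adjusted p = 0.00365). The p27 ubiquitin ligase subunit SKP2 stood at -0.61 ± 0.36 (adjusted p = 0.255) and at -1.67 ± 0.39 without the 14 h array (adjusted p = 0.0159), with its other 2 probe sets moving the opposite way. CDKN1A, which encodes p21, stood at -0.02 ± 0.53, PSMB5, the subunit that bortezomib binds, at 0.03 ± 0.26, PSMB6 at -0.46 ± 0.26, PSMB7 at 0.68 ± 0.26 and PSMA7 at -0.26 ± 0.27. These means hid opposite values, since CDKN1A stood at -2.38, 1.27 and 0.54 at 14 h, 24 h and 48 h against the untreated array of the series, PSMB5 at -0.75, 0.53 and 0.94 and PSMA7 at -1.50, 0.39 and 0.62. Leaving out 14 h put CDKN1A at 1.08 ± 0.58 (adjusted p = 0.220), PSMB5 at 0.52 ± 0.28 (adjusted p = 0.221), PSMB6 at 0.10 ± 0.28, PSMA7 at 0.40 ± 0.29 and PSMB7, past the threshold, at 1.13 ± 0.28. CCNB1 stood at -1.22 ± 0.47 and the stress gene DDIT3 at 3.51 ± 1.41 (adjusted p = 0.103). With the title number as a block CCNB1 (adjusted p = 0.0486), PSMB7 (adjusted p = 0.0447) and DDIT3 (adjusted p = 0.00302) passed.

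**Figure D2:**
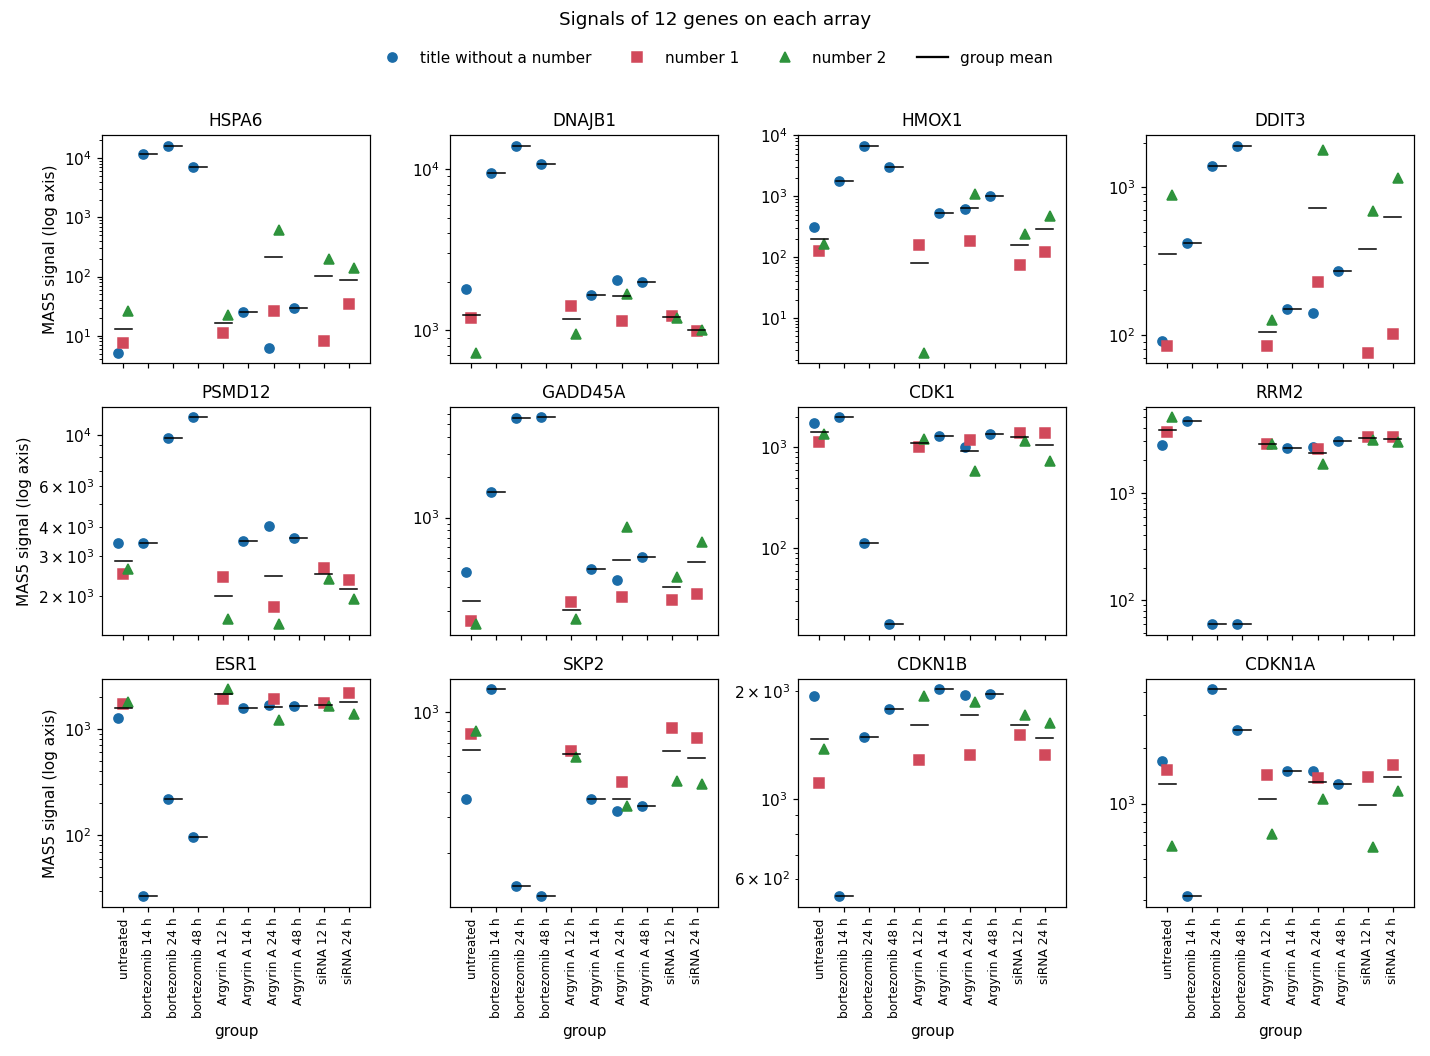
MAS5 signal (log axis) of 12 genes on each of the 17 arrays, grouped by treatment and time, with points for arrays and bars for group means. HSPA6 sits at 11847, 16395 and 7062 in the 3 bortezomib arrays against 5.20 in the untreated array of their series, while CDK1 and RRM2 are low at 24 h and 48 h only.

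Bortezomib was then set against Argyrin A at the matched times of 14 h, 24 h and 48 h, at doses that the labels do not give. Heat shock genes stood higher after bortezomib, with HSPA6 at 8.11 ± 1.04 and 15 of 18 list members called (16 adjusted over the list alone). So did genes of the 19S particle, of which 10 of 18 passed (13 adjusted over the list alone). Estrogen receptor targets (18 of 24), luminal markers (15 of 16), histone genes (11 of 11) and mitosis genes (24 of 28) stood lower. With an estimated correlation these 6 list tests did not pass, and without the 14 h array 8 luminal markers were lower. ESR1 differed by -3.93 ± 0.25 and CDK1 by -2.62 ± 0.29 (-4.24 ± 0.36 without the 14 h array). CDKN1B was lower after bortezomib than after Argyrin A, by -0.84 ± 0.22 (adjusted p = 0.0167), but stood at -0.32 without the 14 h array (adjusted p = 0.425).

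In limma's test 4291 genes differed, 1737 higher and 2554 lower after bortezomib, with 911 and 1600 at 2-fold or more. At 24 h and 48 h alone 3163 differed, 1208 higher and 1955 lower, of which 2631 had been called in the same direction with 14 h and 3 in the opposite one. The count was 2449 without the series term, 2132 in a fit to these arrays alone and 2551 with the times of each compound as replicates. The largest differences were those of HSPA6, CCL26 (4.74 ± 0.30), RGS2 (4.23 ± 0.34), CRYAB (4.10 ± 0.44), ZFAND2A (3.79 ± 0.37), ATF3 (3.69 ± 0.76), DUSP1 (3.69 ± 0.26), the lipase LIPG (3.67 ± 0.31), INHBA (3.66 ± 0.33) and GABARAPL1 (3.46 ± 0.28). The largest in the other direction were those of AGR3 (-6.49 ± 0.33), RAMP3 (-5.39 ± 0.42), CLIC3 (-5.20 ± 0.20, adjusted p = 1.68e-06), SOX3 (-5.18 ± 0.57), MGP (-5.17 ± 0.63), GATA3-AS1 (-5.12 ± 0.30), AMIGO2 (-5.10 ± 0.41), HMCN1 (-5.07 ± 0.26), LINC00052 (-5.06 ± 0.20) and IGFBP5 (-5.06 ± 0.31).

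The heat shock list had a median of 1.91 and adjusted p = 8.39e-10, or 0.0722 with an estimated correlation. The 19S list had a median of 0.76 and adjusted p = 2.67e-04, or 0.475 with an estimated correlation. It was led by PSMD1 (1.21 ± 0.35), PSMD12 (1.09 ± 0.23), PSMC4 (1.01 ± 0.23) and PSMD3 (0.85 ± 0.24). At 24 h and 48 h alone 13 of its 18 members passed, PSMD12 stood at 1.64 ± 0.28, and PSMD3 did not pass. In the 20S core PSMB7 (0.83 ± 0.21) and PSMB3 (0.81 ± 0.27) were higher, 1 gene of 13 passed when adjusted over the list alone, and the list had a median of 0.39 and adjusted p = 0.0118, or 0.647 with an estimated correlation. At 24 h and 48 h alone 4 genes of the 20S core passed (12 adjusted over the list alone), with a median of 0.71 and adjusted p = 1.88e-05, or 0.324 with an estimated correlation, PSMB7 stood at 1.30 ± 0.25 and PSMB3 was no longer called (0.98, adjusted p = 0.0530). Of 18 ribosome biogenesis genes 9 were higher (9 adjusted over the list alone), led by RRP12 (1.99 ± 0.26) and DDX21 (1.31 ± 0.20). The median was 0.60 over the whole list, with adjusted p = 2.16e-04, or 0.294 with an estimated correlation. The adaptor list had 10 of 17 higher and adjusted p = 2.47e-05, or 0.0722 with an estimated correlation. The ATF4 list had 7 higher and 1 lower and adjusted p = 0.00132, or 0.647 with an estimated correlation.

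Of 28 mitosis genes 24 were lower (26 adjusted over the list alone). The median was -1.75 over the whole list, with adjusted p = 2.21e-09, or 0.513 with an estimated correlation. Of 27 S phase genes 16 were lower and 1 higher, with a median of -0.95 and adjusted p = 2.43e-04, or 0.598 with an estimated correlation. DLGAP5 (-3.24 ± 0.43), TOP2A (-2.76 ± 0.32), RRM2 (-3.12 ± 0.23) and TK1 (-2.51 ± 0.19) led them. The medians were -2.70 and -1.97 without the 14 h array, where TOP2A stood at -4.15 ± 0.39, RRM2 at -5.10 ± 0.28 and TK1 at -3.87 ± 0.23. All 11 histone genes were lower, with adjusted p = 5.35e-07, or 0.0877 with an estimated correlation. Of 24 estrogen receptor targets 18 were lower (20 adjusted over the list alone). The median was -1.53 over the whole list, with adjusted p = 2.07e-08, or 0.0722 with an estimated correlation. Of 16 luminal markers 15 were lower, with a median of -1.74 and adjusted p = 8.39e-10, or 0.0722 with an estimated correlation, against 8 and a median of -0.66 without the 14 h array. Of 23 interferon response genes 12 were lower, led by OAS1 (-3.51 ± 0.66) and IFI27 (-3.08 ± 0.81), with adjusted p = 0.00883, or 0.647 with an estimated correlation. At 24 h and 48 h alone 6 of them were lower, and IFI27 was no longer called (adjusted p = 0.0509). Metallothioneins were lower (6 of 8, adjusted p = 0.00589, or 0.566 with an estimated correlation), as were all 3 immunoproteasome genes. Hypoxia targets (4 of 21 higher, adjusted p = 0.0313, or 0.674 with an estimated correlation) and cytosolic ribosomal genes (0 of 23 in limma's test, adjusted p = 7.04e-04, or 0.647 with an estimated correlation) lay higher as lists. Immediate early genes and NRF2 targets passed as lists only without the 14 h array, with adjusted p = 0.00561 and adjusted p = 0.00110, or adjusted p = 0.147 and adjusted p = 0.556 with an estimated correlation. In that fit 14 heat shock, 11 adaptor, 6 ribosome biogenesis, 6 ATF4 and 3 hypoxia genes were higher. Lower were 26 mitosis, 20 S phase, 13 estrogen receptor target (with 1 higher), 10 histone and 6 metallothionein genes.

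Among the genes followed throughout, CKS1B (-0.94 ± 0.18), CCNE2 (-1.09 ± 0.31, with its other probe set moving the opposite way) and TFF1 (-0.66 ± 0.18) were lower after bortezomib than after Argyrin A, and PSMB7 was higher. TFF1 was higher without the 14 h array, by 0.94 (adjusted p = 0.0132), while CKS1B stood at -1.52 ± 0.22 (adjusted p = 0.00136) and CCNE2 at -2.21 ± 0.38 (adjusted p = 0.00299). The others missed the threshold: CDKN1A differed by 0.01 ± 0.42, SKP2 by -0.16 ± 0.29, PSMB5 by 0.07 ± 0.21, PSMB6 by -0.11 ± 0.20, PSMA7 by 0.03 ± 0.22, HMOX1 by 2.18 ± 0.88, DDIT3 by 2.37 ± 1.12 and CCNB1 by -0.86 ± 0.37. SKP2 stood at -1.13 without the 14 h array (adjusted p = 0.0377), CDKN1A at 1.12 (adjusted p = 0.138), PSMB5 at 0.58 (adjusted p = 0.114), PSMB6 at 0.44 (adjusted p = 0.220) and PSMA7 at 0.71 (adjusted p = 0.0719). DDIT3 passed with the title number as a block (adjusted p = 0.00374).

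**Figure D3:**
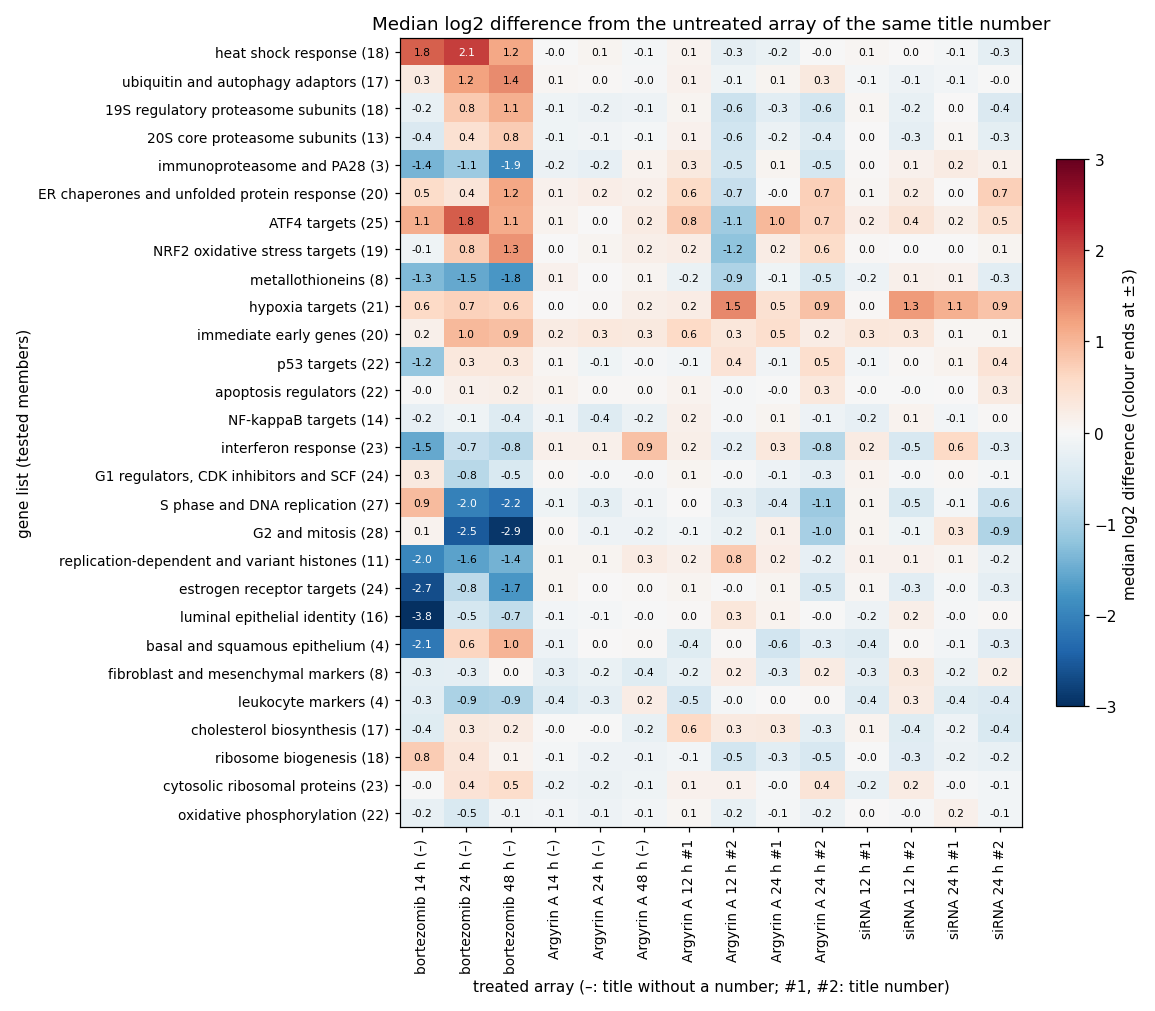
Median log2 difference of each of the 28 gene lists from the untreated array of the same title number, on each of the 14 treated arrays, coloured from lower to higher. The bortezomib columns carry the deepest colours, with heat shock medians of 1.80, 2.07 and 1.16, while the mitosis medians of -0.99 and -0.91 at 24 h lie in the number 2 arrays of Argyrin A and siRNA.

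Argyrin A at 24 h, with 3 arrays against 3, was the replicated test of that compound. Genes of DNA replication fell together as a list, with a median of -0.70 over 27 genes (adjusted p = 7.97e-14, or 0.453 with an estimated correlation). The helicase subunit MCM4 had a signal of 597 ± 201 (SD, n = 3) against 1181 ± 333 (SD, n = 3), a log2 difference of -0.98 ± 0.19. Lists of ribosome biogenesis genes and of 19S and 20S proteasome subunits were also lower, and ATF4 targets, immediate early genes and hypoxia targets were higher. None of these 6 list calls held with an estimated correlation. MCM4 was the only S phase gene past the threshold adjusted over the list alone. The S phase medians were -0.29 in the unnumbered array, -0.43 in number 1 and -1.09 in number 2.

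Single genes did not pass: limma's test called 0 of 12558 genes, with 833 at an unadjusted p under 0.05, where 628 would fall by chance, and a lowest adjusted p of 0.0732 for the long noncoding RNA LOC101928087 (47.9 ± 9.98 against 4.67 ± 2.67, n = 3 each, log2 1.67 ± 0.19). The median 95% confidence interval of a gene's log2 difference reached 0.56 to each side. Next among the higher values came TESK2 (1.61 ± 0.26), PLEKHF1 (1.60 ± 0.30), TRIB2 (1.09 ± 0.17) and FBXL19-AS1 (0.90 ± 0.18). Lower values were led by SNX8 (-1.63 ± 0.28), PGAM5 (-1.24 ± 0.18), SLC12A4 (-1.23 ± 0.25), MCM4 and CCDC137 (-0.90 ± 0.17). The transcript of p27, CDKN1B, had signals of 1715 ± 340 and 1475 ± 423 (0.23 ± 0.23, adjusted p = 0.867), and SKP2 had 371 ± 69.3 and 648 ± 243 (-0.71 ± 0.29, adjusted p = 0.735). CCNE2 stood at -1.05 ± 0.32, HMOX1 at 1.36 ± 0.90, DDIT3 at 0.95 ± 1.15, CCNB1 at -0.48 ± 0.38, PSMA7 at -0.48 ± 0.22, PSMB6 at -0.35 ± 0.21, TFF1 at -0.22 ± 0.19, PSMB7 at -0.21 ± 0.21, CDKN1A at 0.16 ± 0.44, CKS1B at -0.09 ± 0.19 and PSMB5 at -0.04 ± 0.21.

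The ribosome biogenesis list had a median of -0.40 and adjusted p = 2.69e-05, or 0.453 with an estimated correlation. The 19S list had a median of -0.35 and adjusted p = 2.39e-04, or 0.729 with an estimated correlation. The 20S list had one of -0.26 and adjusted p = 0.00106, or 0.764 with an estimated correlation. The mitosis list lay lower at -0.36, with adjusted p = 0.00173, or 0.813 with an estimated correlation. Its median was -0.99 in the number 2 array, against 0.14 in number 1 and -0.14 in the unnumbered one. The oxidative phosphorylation list stood at -0.16 with adjusted p = 0.00531, or 0.740 with an estimated correlation. ATF4 targets stood at 0.60 (adjusted p = 0.00371, or 0.813 with an estimated correlation), immediate early genes at 0.49 (adjusted p = 0.00279, or 0.261 with an estimated correlation) and hypoxia targets at 0.48 (adjusted p = 0.0108, or 0.813 with an estimated correlation). In the unnumbered array, number 1 and number 2 the ATF4 medians were 0.02, 0.98 and 0.68 and the hypoxia medians 0.03, 0.46 and 0.89. In the same order they were -0.16, -0.32 and -0.49 for ribosome biogenesis, -0.17, -0.32 and -0.55 for 19S, -0.11, -0.17 and -0.38 for 20S, -0.15, -0.06 and -0.18 for oxidative phosphorylation and 0.31, 0.51 and 0.23 for immediate early genes. The ER list passed only with the title number as a block (median 0.29, adjusted p = 0.0871, or 0.0348 with the block), with adjusted p = 0.842 with an estimated correlation in the fit without it. Its medians were 0.19 in the unnumbered array, -0.01 in number 1 and 0.73 in number 2. Within the ATF4 list VEGFA stood at 1.04, PHGDH at 1.02 and ASNS at 0.98, and within the immediate early list FOS stood at 1.52, names chosen after their values were seen.

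At 12 h of Argyrin A, with 2 arrays against 3, immediate early genes rose as a list, with a median of 0.48. Hypoxia targets rose with one of 0.73 (adjusted p = 6.71e-06, or 0.735 with an estimated correlation), from medians of 1.45 in number 2 and 0.21 in number 1. EGR1, an immediate early transcription factor, had a signal of 907 ± 112 (SD, n = 2) against 183 ± 75.0 (SD, n = 3), a log2 difference of 2.36 ± 0.37 (adjusted p = 0.522). With KLF10, named after its values were seen (0.88 ± 0.24), it was 1 of 2 genes past the threshold adjusted over the list alone. At 12 h only the immediate early list held both ways. It had adjusted p = 6.71e-06, or 0.0414 with an estimated correlation.

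In limma's test 0 genes passed at 12 h, with 484 at an unadjusted p under 0.05, fewer than the 628 expected by chance. The unadjusted counts given further on for comparisons of Argyrin A and siRNA also lay under 628, so none showed an excess. After EGR1 the higher values were led by PLEKHF1 (1.89 ± 0.35), LOC101928087 (1.18 ± 0.22), TRIB2 (1.16 ± 0.20) and CCDC142 (1.09 ± 0.21). The lower were led by BMAL2 (-1.87 ± 0.25, adjusted p = 0.314), NUDT10 (-1.76 ± 0.39), SLC12A4 (-1.57 ± 0.30), GHRL (-1.39 ± 0.31) and RAD52 (-1.11 ± 0.21). Cholesterol genes lay higher as a list, with a median of 0.36 (adjusted p = 0.00137, or 0.740 with an estimated correlation). So did histone genes at 0.61 (adjusted p = 0.00813, or 0.733 with an estimated correlation) and luminal markers at 0.19 (adjusted p = 0.0396, or 0.735 with an estimated correlation, and 0.0662 with the title number as a block). Lower were ribosome biogenesis genes at -0.28 (adjusted p = 9.85e-05, or 0.722 with an estimated correlation), NRF2 targets at -0.44 (adjusted p = 0.00137, or 0.758 with an estimated correlation) and metallothioneins at -0.56 (adjusted p = 0.00396, or 0.735 with an estimated correlation). Also lower were 19S genes at -0.24 (adjusted p = 0.00813, or 0.740 with an estimated correlation), 20S genes at -0.18 (adjusted p = 0.0230, or 0.758 with an estimated correlation) and ATF4 targets at -0.31 (adjusted p = 0.0458, or 0.933 with an estimated correlation). The 2 arrays went opposite ways in 4 of these lists. In number 1 the medians were 0.07 for 19S, 0.13 for 20S, 0.78 for ATF4 and 0.23 for NRF2, and in number 2 they were -0.64, -0.60, -1.06 and -1.20. Most of the other lists moved the same way in both arrays but further in number 2: histones 0.15 and 0.77 in numbers 1 and 2, luminal markers 0.04 and 0.34, metallothioneins -0.19 and -0.93, ribosome biogenesis -0.09 and -0.55. Cholesterol genes stood at 0.60 and 0.28. Without the series term the direction of the ATF4 and histone lists turned, to 0.03 and -0.19.

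The genes followed throughout stood at 12 h at 0.29 ± 0.27 for CDKN1B, -0.03 ± 0.51 for CDKN1A, -0.21 ± 0.34 for SKP2, -0.05 ± 0.25 for PSMB5, -0.28 ± 0.25 for PSMB6, -0.28 ± 0.25 for PSMB7 and -0.26 ± 0.26 for PSMA7. HMOX1 stood at -1.62 ± 1.06 (0.32 in number 1 and -3.36 in number 2), with -1.44 ± 1.35 for DDIT3 (-0.01 and -2.67), -0.40 ± 0.45 for CCNB1, 0.01 ± 0.38 for CCNE2, 0.04 ± 0.22 for TFF1 and under 0.01 in size for CKS1B. Between 12 h and 24 h of Argyrin A, the ATF4 list rose (median 0.91, adjusted p = 2.86e-07, or 0.626 with an estimated correlation). So did the NRF2 list (0.67, adjusted p = 2.86e-07, or 0.626 with an estimated correlation) and the ER list (0.43, adjusted p = 0.0129, or 0.680 with an estimated correlation). In number 1 the NRF2 median went from 0.23 to 0.21 and the ER median from 0.56 to -0.01, and in number 2 they went from -1.20 to 0.55 and from -0.70 to 0.73. The ATF4 median went from 0.78 to 0.98 in number 1 and from -1.06 to 0.68 in number 2. The S phase list fell (-0.54, adjusted p = 5.02e-10, or 0.449 with an estimated correlation). The cholesterol list fell too (-0.49, adjusted p = 0.00371, or 0.626 with an estimated correlation) and the histone list (-0.32, adjusted p = 0.00443, or 0.449 with an estimated correlation, and 0.05 without the series term). The G1, mitosis and hypoxia lists fell with medians of -0.23, -0.29 and -0.36 and adjusted p = 0.0413 each, or adjusted p = 0.449, adjusted p = 0.833 and adjusted p = 0.684 with an estimated correlation. With the title number as a block the G1 and hypoxia lists did not pass (adjusted p = 0.0507 and adjusted p = 0.0785). In number 1 the medians of mitosis (-0.08 to 0.14), hypoxia (0.21 to 0.46) and histone genes (0.15 to 0.20) went the other way, and in number 2 they went from -0.19 to -0.99, from 1.45 to 0.89 and from 0.77 to -0.24.

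No gene passed between 12 h and 24 h in limma's test (0 called, 415 at an unadjusted p under 0.05, lowest adjusted p 0.786). Adjusted over the list alone, 1 immediate early gene fell, EGR1 (-1.71 ± 0.37, named after its values were seen). The highest values were PCDHA5 (1.65 ± 0.37), BMAL2 (1.57 ± 0.25), PRDM1 (1.53 ± 0.33), C5orf63 (1.45 ± 0.28) and RAD52 (1.15 ± 0.21). The lowest were CCDC142 (-1.26 ± 0.21), NKAIN1 (-1.25 ± 0.26), ANG (-1.16 ± 0.21), DLX1 (-1.02 ± 0.21) and MINK1 (-0.97 ± 0.20). Against the untreated array of the same number, HMOX1 went from 0.32 to 0.50 in number 1 and from -3.36 to 2.63 in number 2, and DDIT3 from -0.01 to 1.29 and from -2.67 to 1.0. In the fit HMOX1 stood at 2.98 ± 1.06, which rested on number 2, DDIT3 at 2.39 ± 1.35, CCNE2 at -1.06 ± 0.38, SKP2 at -0.51 ± 0.34, PSMA7 at -0.22 ± 0.26, TFF1 at -0.26 ± 0.22, CDKN1A at 0.19 ± 0.51, and CDKN1B, CKS1B, CCNB1, PSMB5, PSMB6 and PSMB7 between -0.09 and 0.06.

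The mean of 14 h, 24 h and 48 h of Argyrin A contains the 24 h arrays and the same untreated arrays as the comparison above, so a likeness between them is built in. In the 3 unnumbered arrays themselves the medians at 14 h, 24 h and 48 h were 0.10, 0.02 and 0.24 for ATF4 targets, 0.004, 0.03 and 0.17 for hypoxia targets and -0.13, -0.29 and -0.10 for S phase genes. In the fit S phase genes had a median of -0.41 (adjusted p = 2.98e-07), ribosome biogenesis genes -0.24 (adjusted p = 3.28e-04), 19S genes -0.25 (adjusted p = 0.00164), 20S genes -0.17 (adjusted p = 0.00698), mitosis genes -0.21 (adjusted p = 0.0231) and oxidative phosphorylation genes -0.12 (adjusted p = 0.0384), each with adjusted p = 0.809 with an estimated correlation. ATF4 targets had a median of 0.50 (adjusted p = 0.00279) and hypoxia targets 0.39 (adjusted p = 0.0173), also with adjusted p = 0.809 with an estimated correlation. Immediate early genes had 0.34 (adjusted p = 0.00269, or 0.225 with an estimated correlation), and ER genes 0.30 (adjusted p = 0.113, or 0.809 with an estimated correlation, and 0.0416 with the title number as a block). No gene passed in limma's test, nor when adjusted over a list alone (0 called, 447 at an unadjusted p under 0.05, lowest adjusted p 0.562). The highest values were TESK2 (1.65 ± 0.27), SP8 (1.42 ± 0.31), LOC101928087 (1.39 ± 0.20), ALPG (1.20 ± 0.25) and HPS4 (0.84 ± 0.17). The lowest were CD82 (-1.79 ± 0.31), KCNIP2 (-1.22 ± 0.29), RAX2 (-1.04 ± 0.24), PHB1P19 (-0.96 ± 0.22) and TTBK1 (-0.84 ± 0.20). CDKN1B stood at 0.18 ± 0.24, SKP2 at -0.45 ± 0.31, CCNE2 at -0.72 ± 0.34, HMOX1 at 1.38 ± 0.95, DDIT3 at 1.13 ± 1.22, CCNB1 at -0.37 ± 0.40, PSMB6 at -0.35 ± 0.22, PSMA7 at -0.30 ± 0.23, and CDKN1A, CKS1B, PSMB5, PSMB7 and TFF1 between -0.20 and 0.10.

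In the arrays labelled siRNA, the proteasome genes were looked at first, since the labels do not name the subunits targeted. Of 34 proteasome genes tested, 8 were lower in all 4 arrays labelled siRNA than in the untreated array of the same number, and 0 by a log2 difference of 1 or more in all 4. Among these 8, ADRM1, a ubiquitin receptor of the 19S particle, lay between -0.25 and -0.89, PSMD3 between -0.10 and -0.99 and PSMC4 between -0.02 and -0.60. In 1 array, siRNA 24 h of number 2, PSMD1 was lower by more than 1, at -1.08. The lowest adjusted p of the 34 genes was 0.9996 in limma's test. The median over the 34 genes at 24 h was 0.06 in number 1 and -0.29 in number 2. These values do not show which subunits were targeted, and the arrays are called by their labels throughout.

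At 24 h, hypoxia targets were higher in both arrays labelled siRNA, with list medians of 1.07 and 0.86. Over 2 arrays against 3 the median was 0.89, with adjusted p = 1.86e-09, or 0.977 with an estimated correlation. NDRG1 stood at 2.01, BNIP3L at 1.56 and P4HA1 at 1.52, names chosen after their values were seen. S phase genes (-0.27, adjusted p = 0.00117), mitosis genes (-0.27, adjusted p = 0.0112), cholesterol genes (-0.34, adjusted p = 0.0112) and ribosome biogenesis genes (-0.25, adjusted p = 0.0112) were lower as lists, each with adjusted p = 0.977 with an estimated correlation. In number 1 and number 2 the medians were -0.06 and -0.64 for S phase, 0.33 and -0.91 for mitosis, -0.16 and -0.45 for cholesterol and -0.17 and -0.22 for ribosome biogenesis genes. With the title number as a block ER genes (0.24, adjusted p = 0.0387) and p53 targets (0.26, adjusted p = 0.0387) passed as well, each with adjusted p = 0.977 with an estimated correlation in the fit without the block. The ER medians were 0.003 in number 1 and 0.71 in number 2, and those of p53 targets 0.10 and 0.42. No gene passed in limma's test (0 called, 421 at an unadjusted p under 0.05, lowest adjusted p 0.514). The highest values were LOC101928087 (1.53 ± 0.22), LIAT1 (1.34 ± 0.34), FBXL19-AS1 (1.33 ± 0.22), WHAMMP2 (1.31 ± 0.33) and TRIB2 (0.86 ± 0.20). The lowest were CD82 (-2.00 ± 0.34), IQSEC2 (-1.77 ± 0.29), P2RX6 (-1.63 ± 0.33), TMPRSS4 (-1.43 ± 0.29) and LOC101929536 (-1.03 ± 0.22). No list member passed when adjusted over the list alone, at 12 h or at 24 h. CDKN1B stood at 0.19 ± 0.27, SKP2 at -0.32 ± 0.34, CDKN1A at 0.44 ± 0.51, HMOX1 at 0.58 ± 1.06, DDIT3 at 0.20 ± 1.35, CCNB1 at -0.34 ± 0.45, CCNE2 at -0.26 ± 0.38, and CKS1B, PSMB5, PSMB6, PSMB7, PSMA7 and TFF1 between -0.17 and 0.18.

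At 12 h the arrays labelled siRNA had higher hypoxia targets (median 0.55, adjusted p = 5.07e-06, or 0.997 with an estimated correlation) and immediate early genes (0.28, adjusted p = 1.38e-04, or 0.0798 with an estimated correlation). The hypoxia medians were 0.04 in number 1 and 1.27 in number 2. No gene passed in limma's test (0 called, 365 at an unadjusted p under 0.05). The highest values were TM6SF2 (2.05 ± 0.42), PCDH10 (1.15 ± 0.19), LOC101928087 (1.11 ± 0.22), ACTRT3 (1.11 ± 0.26) and LOC100289361 (0.92 ± 0.20). The lowest were DCAKD (-1.78 ± 0.30), GRIK5 (-1.65 ± 0.33), KIR3DX1 (-1.61 ± 0.32), ST6GALNAC5 (-1.50 ± 0.27) and KDM8 (-1.42 ± 0.29). The genes followed throughout lay between -0.34 (DDIT3) and 0.32 (CDKN1B). From 12 h to 24 h the mitosis list fell (-0.28, adjusted p = 0.00509, or 0.964 with an estimated correlation), as did immediate early genes (-0.21, adjusted p = 0.00489, or 0.175 with an estimated correlation). The mitosis median went from 0.09 to 0.33 in number 1 and from -0.14 to -0.91 in number 2, so the fall came from number 2. With the title number as a block 9 lists passed in place of 2, the others being p53 targets (adjusted p = 0.0152), cholesterol (adjusted p = 0.0374), heat shock (adjusted p = 0.0462), G1, hypoxia, interferon and S phase genes (adjusted p = 0.0473 each). With an estimated correlation in the fit without the block these 7 had adjusted p = 0.414 (G1) and adjusted p = 0.964 (the other 6). Over the step the hypoxia median went from 0.04 to 1.07 in number 1 and from 1.27 to 0.86 in number 2. In limma's test 0 genes passed, with 228 at an unadjusted p under 0.05. Over that step the genes followed throughout lay between -0.33 (CCNB1) and 0.78 (HMOX1). The highest values were MYO7B (1.39 ± 0.32), DCAKD (1.37 ± 0.32), IL16 (1.31 ± 0.30), EFNA3 (1.18 ± 0.25) and FBXL19-AS1 (1.04 ± 0.22). The lowest were TMPRSS4 (-1.89 ± 0.30), CD82 (-1.67 ± 0.35), P2RX6 (-1.67 ± 0.34), MC2R (-1.38 ± 0.30) and PCDH10 (-1.11 ± 0.20).

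The arrays labelled siRNA were set directly against Argyrin A as the mean of 12 h and 24 h. Cholesterol synthesis genes were lower in the arrays labelled siRNA, with a median of -0.42 and adjusted p = 3.48e-07, or 0.649 with an estimated correlation. Metallothioneins were higher, at 0.39 and adjusted p = 0.00295, or 0.730 with an estimated correlation. Against their untreated arrays, the metallothionein medians at 12 h and 24 h were -0.16 and 0.13 for siRNA and -0.19 and -0.14 for Argyrin A in number 1, and 0.14 and -0.31 against -0.93 and -0.46 in number 2. Those of cholesterol genes were 0.10 and -0.16 against 0.60 and 0.29 in number 1, and -0.35 and -0.45 against 0.28 and -0.29 in number 2. Smaller shifts of other lists passed with medians within 0.15 of 0: ribosome biogenesis (0.14, adjusted p = 0.00264), oxidative phosphorylation (0.08, adjusted p = 0.00672), 19S (0.12, adjusted p = 0.00690), 20S (0.12, adjusted p = 0.00690). The others were S phase (0.14, adjusted p = 0.00829), cytosolic ribosomal (-0.15, adjusted p = 0.0145, and 0.02 under quantile normalization), immediate early (-0.12, adjusted p = 0.0195) and G1 genes (0.09, adjusted p = 0.0388). With an estimated correlation these 8 gave, in that order, adjusted p = 0.649, adjusted p = 0.730, adjusted p = 0.821, adjusted p = 0.866, adjusted p = 0.967, adjusted p = 0.967, adjusted p = 0.471 and adjusted p = 0.471.

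No gene passed between them in limma's test (0 called, 407 at an unadjusted p under 0.05, lowest adjusted p 0.9999), and the median 95% confidence interval reached 0.48 on the log2 scale to each side. The highest values were CABP4 (1.03 ± 0.26), C20orf181 (0.99 ± 0.25), ABTB3 (0.76 ± 0.15), NBEAL1 (0.69 ± 0.16) and COX20 (0.63 ± 0.16). The lowest were GTF2IP20 (-1.79 ± 0.28), PTPRO (-1.34 ± 0.27), the mitochondrial gene ND2 (-1.17 ± 0.24), IQSEC2 (-1.02 ± 0.21) and LOC101929536 (-0.91 ± 0.16). Adjusted over the list alone, PSMB9 of the immunoproteasome was higher (0.90 ± 0.26) and NFKB2 of the NF-kappaB list lower (-0.92 ± 0.23) in the arrays labelled siRNA, both named after their values were seen. The genes followed throughout lay between -0.02 (TFF1) and 0.38 (CCNE2). Taken at single times, siRNA against Argyrin A also called 0 genes in limma's test, with 357 at an unadjusted p under 0.05 at 12 h and 267 at 24 h.

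Fold changes of the treatments were correlated across genes, which are not independent replicates. At 24 h, Argyrin A and the arrays labelled siRNA correlated at 0.585, where unchanged groups against the same untreated arrays gave 0.427, with covariances of 0.0688 and 0.04601. At 12 h the pair gave 0.493 against 0.456, with covariances of 0.0575 and 0.0574. Argyrin A at 24 h and bortezomib gave 0.218 against 0.408, with covariances of 0.0696 and 0.0458, and the arrays labelled siRNA at 24 h and bortezomib gave 0.132 against 0.174, with covariances of 0.0424 and 0.0230. Argyrin A and bortezomib as means of 3 times gave 0.241 against 0.645, with covariances of 0.0702 and 0.0764. The spread of bortezomib fold changes (SD 0.934) can itself lower r, so only their covariances compare with simulation. The 3 untreated arrays cannot be split into parts of at least 2, so part of any excess may come from the shared controls. Arrays of number 1 and of number 2 stood in both groups, and what arrays of the same number share was not simulated, so an excess may come from that too. Between arrays that share no untreated array, the 2 highest correlations of 64 were 0.22, those of Argyrin A 24 h of number 1 with Argyrin A 24 h and siRNA 24 h of number 2. Other pairs of the same treatment and time lay lower. Argyrin A 24 h of the unnumbered series stood at 0.10 with number 1 and 0.06 with number 2. Numbers 1 and 2 correlated at 0.13 for siRNA 24 h, at 0.03 for siRNA 12 h and at 0.006 for Argyrin A 12 h. Across treatments, siRNA 24 h of number 1 stood at 0.07 with Argyrin A 24 h of number 2. Bortezomib correlated with Argyrin A 24 h and siRNA 24 h of number 2 at 0.158 and 0.150 at 24 h, at 0.141 and 0.126 at 48 h and at -0.003 and 0.02 at 14 h. With those of number 1 bortezomib stood at 0.0314 and -0.0188 at 24 h, at 0.0109 and -0.0397 at 48 h and at -0.0302 and -0.0257 at 14 h. Single arrays differed from their own untreated array by more than 2-fold in 4688, 3089 and 3589 genes after bortezomib at 14 h, 24 h and 48 h, in 535 to 1274 genes after Argyrin A and in 521 to 819 genes in the arrays labelled siRNA.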

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

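The tests of the 3 patterns weighed here were chosen after the patterns had been seen, and the counts of other splits of the samples were planned, except that of bortezomib at 24 h and 48 h alone.

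Bortezomib at 14 h differed from the mean of 24 h and 48 h in 3497 genes, 1772 higher and 1725 lower, in a limma test of the difference itself. S phase genes (26 of 27) and mitosis genes (24 of 28) were higher at 14 h, luminal markers (13 of 16), estrogen receptor targets (10 of 24) and 19S genes (12 of 18) lower. On that array 58 genes were bright or dim as on no other array, against 0 on each other array, a count that restates how the array stands apart and so decides nothing on cells of another source. RNA degradation is argued against by an ACTB 3 prime to 5 prime ratio of 1.71, where the other arrays of the series reached 14.7. A response of MCF-7 cells alone is argued against by CDKN2A, a gene that MCF-7 cells lack by deletion, with a signal of 1516 there and at most 99 elsewhere. Its HSPA6 signal of 11847 lay with those of the other bortezomib arrays, so cells of another source that were exposed to the compound may be behind the array, which stays open.

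Mitosis genes were lower after bortezomib at 24 h and 48 h. RNA degradation is argued against by the 48 h array, where the list median was -2.91 with an SE of 0.22 over its 28 members, while the ACTB ratio of 6.96 lay near the 5.34 of the untreated array of the series. Cells of the source of the numbered arrays are argued against by the 5 genes bright on all of those and dim on the unnumbered arrays without bortezomib, with a median of 5.88 and an SE of 0.29 at 24 h and 5.44 and 0.34 at 48 h, where numbered arrays had at least 9.88. Cells of a further source stay open: 0 genes were bright or dim on the 24 h or the 48 h array alone, but a source of both would put its genes on both, and the 26 genes of the reverse kind had medians of 8.14 and 7.78, between the 9.75 of the untreated array of the series and the 6.77 at 14 h. A loss of cycling cells under bortezomib may be another candidate explanation, untested with 1 array per time.

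Mitosis genes were also lower at 24 h in the number 2 arrays of both Argyrin A (-0.99) and siRNA (-0.91), each in 28 of 28 members, while the number 1 arrays stood at 0.14 and 0.33. An unusual untreated array of number 2 is argued against by the 12 h arrays of that number, whose lower median was -0.19 against the same untreated array. RNA degradation is argued against by an ACTB ratio of at most 1.59 on those arrays, where other numbered arrays reached 2.17. A difference between the rounds in cell density or handling, or in the strength of both treatments, stays open and was not tested.

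In the comparison of bortezomib with untreated cells, 180 of 1151 probe sets with several gene symbols passed, 79 higher and 101 lower, and 302 of 3048 probe sets with no symbol passed, 115 higher and 187 lower. These probe sets entered none of the report's comparisons, and they named no gene here.

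Other splits of the same arrays were counted in fits of 2 groups with the series term, in which all times of a group shared 1 mean, unlike the fits to the groups compared with a mean for each time (675 and 2132 genes for bortezomib against untreated cells and against Argyrin A). For bortezomib against untreated cells the real split gave 2 genes and the highest other 676, from the split that set the unnumbered untreated array with bortezomib at 24 h and 48 h against the rest. With the series term that split sets bortezomib at 14 h against the other 3 unnumbered arrays, which points to the 14 h array standing apart. As many genes as the real split came from 2 of 10 splits, which are too few for a share under 0.05. For Argyrin A at 24 h the real split gave 0 and the highest other 7, and the 10 of 10 splits are again too few. For Argyrin A over 3 times the real split gave 0 genes and the highest other 155, and with a real count of 0 all 56 of 56 splits give as many, which decides nothing. That other split set all unnumbered arrays on the same side, so with the series term its genes came from Argyrin A at 24 h of number 2 against the 3 other numbered arrays, which points to that array standing apart. For siRNA against Argyrin A the real split gave 0, so that 100 of the 100 splits drawn give as many and nothing is decided, the highest other being 579, from the split that set arrays of title number 1 against the rest, which points to a structure of the samples by that number. That split parts no arrays of the same number, while the real one parts them.

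For bortezomib against Argyrin A at 14 h, 24 h and 48 h the real split gave 1355 genes and 3 of 56 splits gave as many, the highest other being 1505, so chance is not excluded. That other split set the bortezomib 14 h array with the numbered Argyrin A arrays, so with the series term its genes came from the 14 h array against the other 5 unnumbered arrays, which points to the 14 h array standing apart. For bortezomib at 24 h and 48 h against Argyrin A the real split gave 3484 genes and the highest other 0. As many genes came from 1 of 20 splits, the real one, which are too few for a share under 0.05.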

How the results depend on the processing

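All settings here were planned, except the list tests without bortezomib at 14 h, chosen after the data had been seen. In each case below the cause was not tested, beyond the smaller number of arrays where arrays were left out. The count for bortezomib against untreated cells was 675 (209 higher, 466 lower) in a fit to the groups compared, 680 with the time points as replicates, and 540 to 2734 with 1 array left out, lowest without the unnumbered untreated array. The count for bortezomib against Argyrin A was 2449 without the series term, 2132 in a fit to the groups compared, 2551 with the time points as replicates, and 3415 to 4390 with 1 array left out. The share of higher calls moved by less than 10 percentage points under every scaling, and the values without rescaling moved nothing. Counts of 0 became 1 at an offset of 2.5% for Argyrin A at 24 h, for siRNA at 12 h and for siRNA at 24 h against 12 h. With 1 array left out they were 0 to 1 for Argyrin A at 12 h and for Argyrin A at 24 h against 12 h, the 1 arising without Argyrin A 12 h number 1. Where a left-out array leaves a group with 1 array, that array is assumed to vary like the other groups.

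Without the series term, directions turned for PSAT1 (-0.72), STARD4 (-0.36), VIM (-0.040), FN1 (1.92) and HSPB8 (-0.58) after bortezomib, for FN1 against Argyrin A (0.31), and for the lists of ATF4 targets (0.034) and histones (-0.19) at 12 h of Argyrin A and histones from 12 h to 24 h (0.045). The likeness of Argyrin A and siRNA at 12 h was then 0.679, that of siRNA at 24 h and bortezomib -0.048, and that of both compounds over 3 times 0.352. ABCC3 turned with the probe set of highest median (0.12), and the cytosolic ribosomal list of siRNA against Argyrin A with quantile normalization (0.022). With 1 array left out, VIM ranged from -0.43 to 3.90 against untreated cells and from -1.12 to 3.20 against Argyrin A, and TFF1 from -1.69 to 0.73 and from -1.49 to 0.93, each turning without bortezomib at 14 h. Of 205 calls of named genes, 141 held without the series term, 154 in a fit to the groups compared, 122 with the time points as replicates and 202 with quantile normalization. Of 90 list calls, 1 held with an estimated correlation, 67 without the series term, 81 with quantile normalization, 89 at an offset of 2.5% and 84 without a filter.

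With the title number as a block, in place of the series term, bortezomib gave 3850 genes against untreated cells and 5242 against Argyrin A, and the other 8 comparisons gave 0. All 205 calls of named genes held with that block and so did 87 of 90 list calls. Beyond the calls given beside their results the block changed no other call.

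Signals near the floor limit what dim genes can show, since between 3.08% and 5.93% of tested genes had a signal under the offset of 15.0 on an array.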

Other observations

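The tests and values in this part were chosen after the data had been seen, and genes are named for their values.

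The 2 series of untreated and Argyrin A arrays differed in which genes were on. Between the 4 unnumbered arrays without bortezomib and the 10 numbered arrays, 26 genes were bright in the first and dim in the second and 5 the other way round. CA2, carbonic anhydrase, had a signal of 3147 ± 201 (SD, n = 4) against 2.69 ± 3.97 (SD, n = 10), AGR3 had 2555 ± 410 against 10.8 ± 12.7, and the caveolin CAV1 had 1473 ± 254 against 27.4 ± 19.2. In the other direction PLS3, an actin bundler, was under 15 on average against 2197 ± 301. PSAT1, an enzyme of serine synthesis, had 10.1 ± 8.19 against 1418 ± 735, and EHF, an epithelial transcription factor, had 25.3 ± 4.73 against 1284 ± 379. Of these, CA2 stayed on in the bortezomib arrays, at 1747, 1575 and 1037, while AGR3 was at 3.70, 17.9 and 13.7. PLS3 and PSAT1 had signals of 2546 and 3610 in the bortezomib 14 h array, against at most 43.9 and 57.8 at 24 h and 48 h. Over all tested genes, 423 had every unnumbered array above every numbered array by more than 1 on the log2 scale, and 168 the reverse.

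Hypoxia targets had list medians of 0.60, 0.68 and 0.64 after bortezomib at 14 h, 24 h and 48 h. Among the other arrays they were highest in the 4 treated arrays of number 2 and in siRNA 24 h number 1. Their list medians were 1.45 and 0.89 after Argyrin A for 12 h and 24 h and 1.27 and 0.86 in the arrays labelled siRNA at 12 h and 24 h. In number 1 the medians were 0.21 and 0.46 after Argyrin A and 0.04 and 1.07 in the arrays labelled siRNA, and in the unnumbered series the 3 Argyrin A arrays stood at 0.004, 0.03 and 0.17. The number 2 array of Argyrin A at 12 h also had a median of -1.06 for ATF4 targets and -1.20 for NRF2 targets, against 0.78 and 0.23 in number 1. The untreated array of number 2 had a DDIT3 signal of 887, against 84.6 in number 1 and 91.3 in the unnumbered one. Interferon response genes had their highest median of all 14 treated arrays, 0.87, after 48 h of Argyrin A.

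The most alike arrays were those of Argyrin A at 14 h and 48 h, at a correlation of 0.977 across genes, with 262 probe sets at the same value, and they were kept as separate samples.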
